A study of Drosophila melanogaster with 2 samples.

How the data were processed

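Chromatin from Drosophila melanogaster embryos was digested with micrococcal nuclease, and libraries were made from mononucleosomal DNA, with adapter-ligated DNA of 150-250 bp taken from an agarose gel, per the labels' protocols. The series held 2 libraries, 1 per group: Toll10b embryos of 2 to 4 h and sorted muscle cells of 14 to 17 h. The muscle library was placed in its group by its tissue label; its genotype label names an elav driver, and this conflict was not resolved. Fragments were aligned to the dm3 genome with Bowtie 0.12.7, per the submitters' processing notes. How fragments with several matches, copies and mate pairs were treated was not given in the sources used here.

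Each deposited file listed 1 fragment per line by chromosome, start and end, without a header, strand or score, so the deposited values are coordinates and every fragment count was computed from them. Starts were read as counted from 0, as is usual for the format, which the files do not state, and coordinates are printed counted from 1 on dm3. All 12 chromosome sequences in the files were used. The Toll10b library had 22069239 fragments on the 5 major arms (95.8%) and the muscle library 24576404 (93.7%). Copies beyond the first of fragments with the same start and end made up 10.5% and 10.9%. They were kept in the main counts because such copies cannot be told from separate molecules cut at the same sites.

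The groups, the 1.5-fold size rule, a first spacing estimate and a set of alternatives were chosen before the data were examined. The main tests planned then concerned promoters, gene lists, core promoter elements and named genes. They need a dm3 annotation or sequence, which was not used here, so the fallback fixed at the same time applied: arms, 1 kb bins, fragment lengths and spacing were compared by the coordinates in the files alone, and no gene-level result, gene list or GC check was computed. A table of gene names on another assembly was left out, since coordinates of different builds were not mixed. Strand balance and the distance between reads of opposite strands were left out because the files hold no strand.

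Fragments were assigned to 1 kb bins by their centres. The ratio of a bin or sequence was the log2 of muscle over Toll10b, scaled by the library totals on 2L, 2R, 3L, 3R and X, with the exact 95% interval of the muscle share of the pooled count. A bin was tested with at least 50 fragments in both libraries together and passed the rule when its whole interval lay beyond 1.5-fold. The rule for naming promoters was carried over to bins: the 10 bins with the largest absolute log2 ratio in each direction among those past the rule, with at least 200 fragments in both libraries together and the same sign when scaled by 4 flanking bins on each side. A fold against a count of 0 used a floor of 3 counts per library. The proximal 1 Mb of an arm was measured from the end of its dm3 sequence, and bins over 5 times the median were called high-count.

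The repeat length was the slope of a line through the first 4 peaks of the histogram of distances up to 1000 bp between centres of fragments of 120 to 180 bp. The histogram was smoothed over 25 bp and divided by its running mean over 185 bp, and high-count bins were left out. Its range over the 5 arms is given as spread, although arms are not replicates. Windows of 200 bp were compared with flanks of 500 bp that start 400 bp away on both sides, and windows with an expected count of at least 10 in each library were used. The spacing estimate described here replaced the first one after the data had been seen. The depleted windows, the 20 kb regions, the comparison of arm tips and the fragment length classes were set after that too.

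The scripts were tested on simulated data. For the 1 kb bins of 2L (21723 tested), 85% of the bins changed 2-fold and 100% of those changed 3-fold or 4-fold were called in the right direction, and 0% of the unchanged bins were called. Simulated repeat lengths were recovered to within 1 bp. Of simulated windows at 0.1 times the mean, 98% were called depleted. The simulated bins had Poisson error only, around 1 density shared by both libraries, and changed bins were increases only. Simulated spacing used regular arrays. These runs check the scripts and do not give error rates for the real libraries. The alternatives tried were 1 copy of each fragment, other scalings, thinning to equal depth, other count minimums, leaving out X, only fragments within 5 bp of 150 bp, leaving out high-count and empty bins, and other settings for spacing and depletion. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.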

Results

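The data were MNase-seq libraries from Drosophila melanogaster embryos. MNase (micrococcal nuclease) cuts the linker DNA between nucleosomes, so that the sequenced fragments mark the DNA that histones or other proteins protected. The series was designed to compare nucleosome occupancy between tissues and stages of the embryo. It held 2 libraries, 1 per group. The first came from embryos of Toll10b mothers collected 2 to 4 h after egg laying. Toll10b is a gain-of-function allele of the Toll receptor, which sets up the dorsoventral axis, and its embryos form mesodermal precursors in place of more dorsal fates. The second came from muscle cells sorted by FACS from dissociated embryos of 14 to 17 h. The genotype label of this library lists an elav driver with a GFP reporter, and elav drivers are neuronal, while its title, source and tissue labels all name muscle; it is called the muscle library here after the tissue label. The Toll10b library held 23047803 fragments and the muscle library 26228401. Stage, tissue, genotype and cell sorting all differed between the libraries, so each difference compares 2 libraries and not 2 conditions. With 1 library per group there was no replicate check and no p-value was computed. The 95% intervals are exact binomial (Clopper-Pearson) intervals unless stated otherwise, and they cover counting error only.

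Fragments were shorter in the muscle library. Its median length was 126 bp (quartiles 109 and 142 bp), against 138 bp (125 and 149 bp) in the Toll10b library, a difference of 12 bp. Fragments below 100 bp, which are too short for a complete nucleosome core, made up 17.5% of the muscle library and 5.22% (interval 5.21% to 5.23%) of the Toll10b library, a ratio of 3.35. Fragments of 120 to 180 bp, the nucleosome-sized class, made up 59.9% and 82.5%. The most common length was 127 bp in muscle and 144 bp in Toll10b. The short share was higher in muscle on each of the 12 chromosome sequences, for example 21.8% against 6.56% on chromosome 4 and 17.3% against 5.09% on X. The lengths follow how far the nuclease digestion went as well as what the DNA was bound by, and the extent of digestion was not measured here.

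**Figure D1:**
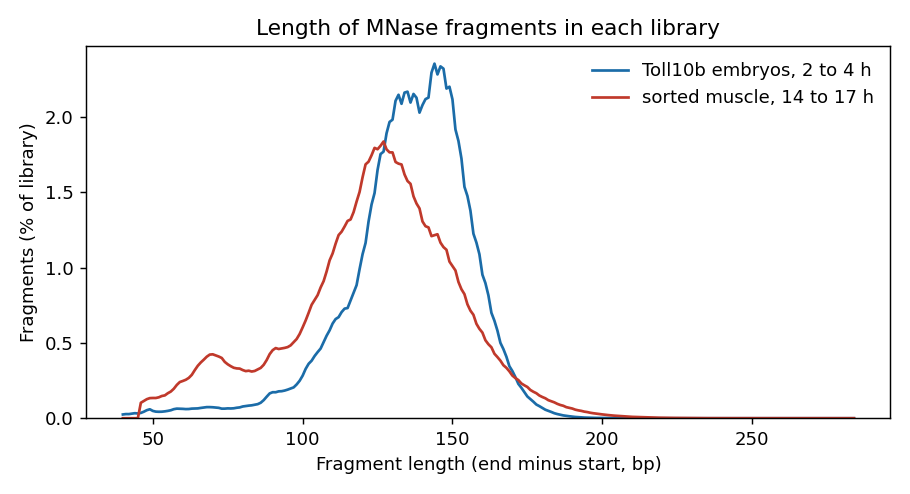
Share of each library (percent of fragments) by fragment length in bp, with 1 line per library. The Toll10b line peaks at 144 bp, while the muscle line peaks at 127 bp and has a shoulder of short fragments near 69 bp.

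Chromosome 4 and the heterochromatic sequences held a larger part of the muscle library. Chromosome 4 is the small chromosome whose genes lie among heterochromatin, and the sequences named Het in the dm3 build are the assembled pericentric heterochromatin. Chromosome 4 had 89.7 fragments per kb in Toll10b (121129 fragments) and 176 per kb in muscle (237999 fragments). Scaled by the library totals on the arms 2L, 2R, 3L, 3R and X, its log2 ratio of muscle over Toll10b was 0.82 (0.81 to 0.83). The heterochromatic sequences of chromosomes 2 and 3 together had a log2 ratio of 0.57, and each was higher in muscle, with 0.49 for 2LHet, 0.64 for 2RHet, 0.60 for 3LHet and 0.49 for 3RHet. Relative to the density of the major arms, chromosome 4 stood at 0.484 in Toll10b and 0.853 in muscle, and the heterochromatin of chromosomes 2 and 3 stood at 0.364 and 0.542.

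The difference on chromosome 4 was found in many of its bins, and its course along the chromosome was not profiled. The 10 densest bins of chromosome 4 held 25.6% of its Toll10b fragments and 19.6% of its muscle fragments. Of its 1192 bins of 1 kb with at least 50 fragments in both libraries together, 711 (59.6%) were higher in muscle by the size rule, in which the whole interval lies beyond 1.5-fold, and 5 were lower. Its median bin had a log2 ratio of 1.17, against 0.17 for the median bin of the major arms. In 2RHet, 833 of 1748 bins were higher and 48 lower, and in 3LHet 758 of 1646 were higher and 46 lower. XHet had a log2 ratio of 0.55, but its 10 densest bins held 93.5% of its Toll10b fragments and 92.4% of its muscle fragments, so this value describes a few dense stretches. Counted by bins, the median bin of XHet stood at 0.77, and 58 of its 137 bins were higher and 3 lower. Bins of low density had higher ratios along the arms too: over 5 equal groups of the arm bins outside the proximal 1 Mb, ordered from the lowest mean density of the 2 libraries to the highest, the median log2 ratio was 0.83, 0.41, 0.19, -0.02 and -0.37. Set against arm bins of like density, the median excess of chromosome 4 was 0.50 and that of the heterochromatin of chromosomes 2 and 3 was 0.39.

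The same direction was found at the centromere-proximal ends of the arms. In the proximal 1 Mb of 2R the median bin had a log2 ratio of 0.99, against 0.09 on the rest of the arm, and 48.1% of the proximal bins were higher in muscle, against 12.8% elsewhere. The proximal and remaining medians were 0.88 and 0.18 on 2L and 0.93 and 0.18 on 3L. The contrast was smaller on X (0.51 and 0.16) and on 3R (0.39 and 0.17). Set against arm bins of like density, the proximal bins of the 5 arms had a median excess of 0.28.

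**Figure D2:**
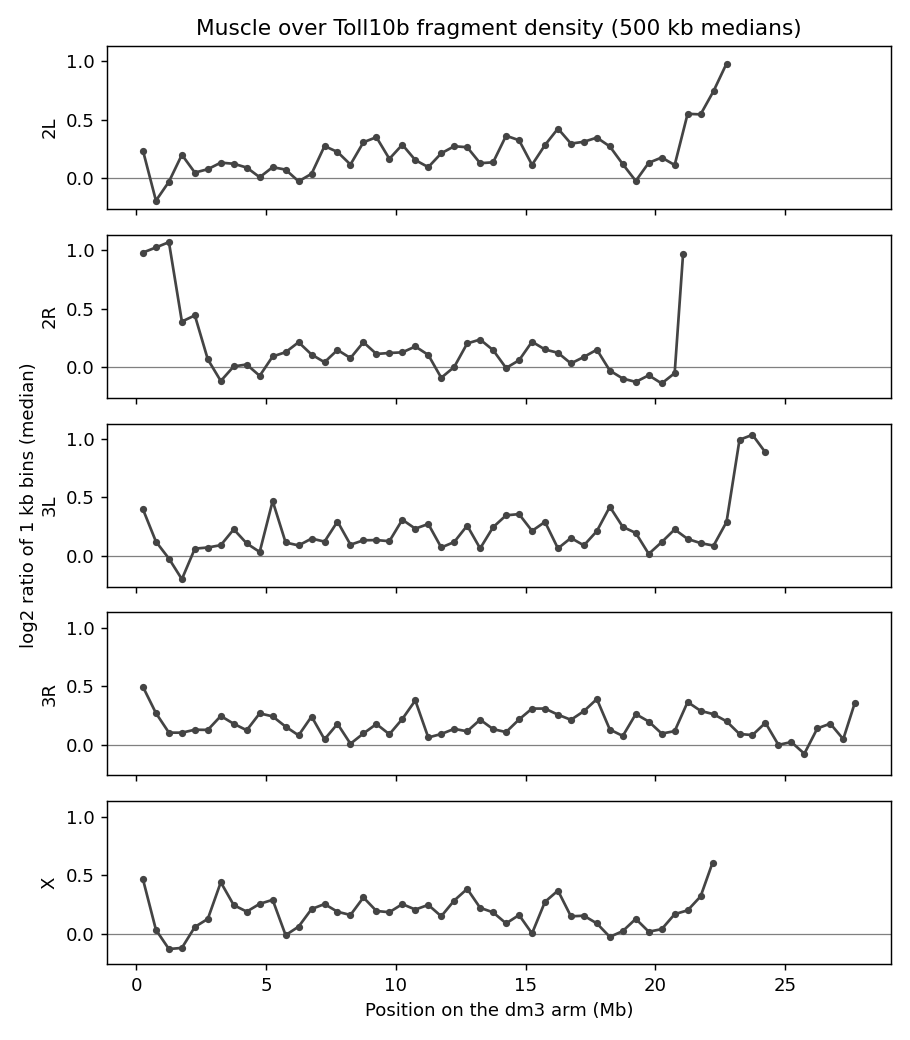
Median log2 ratio of muscle over Toll10b fragment density in 1 kb bins, per stretch of 500 kb (points), against the position in Mb on the dm3 coordinates of each of the 5 major arms, scaled by library totals. The ratio rises toward the right end of 2L, 3L and X and the left end of 2R, and less at the left end of 3R, which are the centromere-proximal ends. The outermost distal stretch stands at 0.96 on 2R, 0.46 on X, 0.40 on 3L, 0.36 on 3R and 0.24 on 2L, and single interior stretches reach 0.42 on 2L, 0.47 on 3L, 0.39 on 3R and 0.44 on X; the last point of 2R, 3R and X covers a shorter stretch.

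X and the autosomal arms took similar parts of both libraries. The density of X over that of the autosomal arms was 0.779 (0.778 to 0.780) in Toll10b and 0.753 (0.752 to 0.754) in muscle. The log2 ratios of the 5 arms lay between -0.04 on X and 0.03 on 3R.

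Within the major arms, 15549 of 112974 bins (13.8%) were higher in muscle and 5132 (4.54%) were lower. The balance depended on the scaling. With library totals, 75.2% of the bins past the rule were higher. With the median bin set to no change, 51.8% were higher (10424 bins, against 9689 lower). With library totals and only fragments within 5 bp of 150 bp, 1215 bins were higher and 1093 lower, of 58953 tested. Bin densities covered a narrower range in muscle, where the 90th percentile of the counts was 3.64 times the 10th, against 7.69 times in Toll10b. Across 112873 bins the log2 counts of the libraries had a Pearson r of 0.79 and a Spearman rho of 0.80; bins are not independent replicates.

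Regions of 20 kb outside the proximal 1 Mb were ranked by their median bin after the data had been seen. The highest of 5620 regions was 3L 40001 to 60000, close to the tip of the arm, with 1023 Toll10b and 3764 muscle fragments, a pooled log2 ratio of 1.72 (1.62 to 1.83) and all 20 of its bins above the arm median. Several others of the 10 highest lay close to the proximal 1 Mb that was left out, such as 2R 1120001 to 1140000 and 3L 23060001 to 23080000, both at 1.15. A region inside X, 11840001 to 11860000, had a ratio of 1.17. Among the lowest were 3L 1760001 to 1780000, with 10071 Toll10b and 7313 muscle fragments and a ratio of -0.62, 2R 11840001 to 11860000 at -0.66, X 820001 to 840000 at -0.62 and 2L 560001 to 580000 at -0.58. All these ratios pool the fragments of a region, while the ranking used its median bin. The median bins of the high regions, in the order named, were 1.83, 1.57, 1.47 and 1.43. Those of the low regions were -0.74, -0.73, -0.67 and -0.64. The 1st and 99th percentiles of the region medians were -0.46 and 1.11. Among the 10 highest, the lowest pooled ratio was 0.55, on 2R 2200001 to 2220000, where the median bin was 1.46. The ranking was not matched on density and went along with it. The 10 highest regions held 350 to 1829 Toll10b fragments, and the 10 lowest held 5503 to 10071. On 3L, Toll10b coverage began only at position 32806, near the highest region, and copy number was not measured. The genes in these regions were not analysed here, because no gene annotation of the dm3 build was used.

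The bins with the largest ratios were covered in 1 library and empty in the other. The rule fixed for promoters, carried over to 1 kb bins, named 10 bins in each direction. All of them were at 0 in 1 library, since a ratio against 0 is unbounded and was ranked first. Most of the 10 higher bins lay together at the tips of 3L and 2R. Lower in muscle were X 3313001 to 3314000, with 4108 Toll10b fragments and 0 in muscle (at least 1525-fold lower, with a floor of 3 counts per library), and 3L 24471001 to 24472000, with 2004 and 0 (at least 744-fold lower). Higher in muscle were 2R 21146001 to 21147000, with 0 and 1613 fragments (at least 483-fold higher), and 2R 942001 to 943000, with 0 and 623 (at least 186-fold higher). With this floor the folds ran from 178 to 1525 for the 10 lower bins and from 70.0 to 483 for the 10 higher bins. The floor replaces the 0 alone, and the exact intervals allow smaller differences: their ends nearest to no change were log2 ratios of -7.17 to -10.28 for the lower bins and 5.82 to 8.62 for the higher bins. Several of these bins had over 5 times the fragments of a median arm bin in the library that covered them, and copy number was not measured.

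Counted over the arms, 44 bins were empty in Toll10b and 57 in muscle while the other library covered them. They formed 7 runs of at least 2 bins in Toll10b and 9 in muscle. The longest was 3L 19001 to 28000, a stretch of 9 kb with 1801 muscle fragments and 0 Toll10b fragments, where 1617 would have been found at the scale of the arms. The next was 2R 21140001 to 21147000, a stretch of 7 kb with 2753 muscle fragments and 0 in Toll10b. Both lie at the distal tips of their arms. Toll10b coverage of 3L began at position 32806, and 2515 muscle fragments lay wholly before it, from position 19673 on. Toll10b coverage of 2R ended at 21139699, and 2781 muscle fragments lay beyond it, up to 21146708. The tips of 2L, 3R and X were covered in both libraries to within 1 kb of each other. In muscle the longest empty run was 2R 18241001 to 18246000, with 1135 Toll10b fragments, followed by 3R 22825001 to 22829000, with 400.

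Nucleosomes were regularly spaced in both libraries. The repeat lengths from the slope over 4 peaks overlapped, while the distance of the first peak did not. From the distances between centres of nucleosome-sized fragments, the repeat length was 183.6 bp in Toll10b (176.9 to 183.9 bp over the 5 arms) and 179.7 bp in muscle (173.1 to 187 bp). It was shorter in Toll10b on 3L (183.7 against 187 bp) and X (176.9 against 182.2 bp), and longer on the other arms. On each of the 5 arms the first peak lay at 187 bp or more in Toll10b and at 178 bp or less in muscle. With the arms together, the peaks lay at 192, 367, 556 and 741 bp in Toll10b and at 178, 363, 543 and 717 bp in muscle. The gap at the first peak was thus not kept at the second. The Toll10b first peak was also broad, with values of 1.019 at 180 bp, 1.021 at 192 bp and 1.019 at 200 bp. Its position alone does not show wider spacing in Toll10b. The height of the first peak differed as well. The first peak, between neighbouring nucleosomes, rose 6.65% above its surroundings in muscle, at 178 bp, and 2.08% in Toll10b, at 192 bp. The fourth peak kept 5.38% of the height of the first in muscle and 28.8% in Toll10b. The estimate fixed beforehand, from left fragment ends without removal of the trend, gave 2 peaks in Toll10b and therefore no repeat length there, so the values above come from a version chosen after this was seen.

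**Figure D3:**
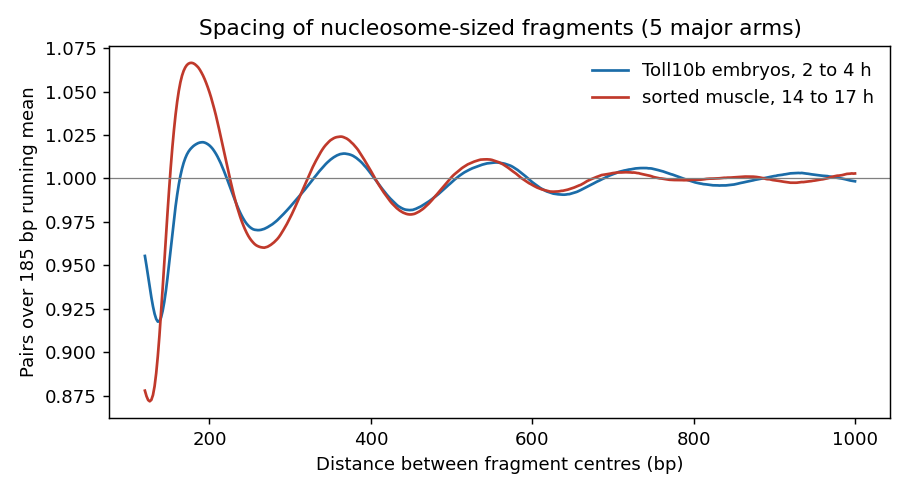
Number of pairs of nucleosome-sized fragments on the 5 major arms, divided by its running mean, against the distance between their centres in bp, with 1 line per library. Both lines have peaks about 180 bp apart, and the first peak is higher in muscle (6.65% at 178 bp) than in Toll10b (2.08% at 192 bp), while later peaks of the muscle line flatten sooner.

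Windows depleted of nucleosome-sized fragments were more numerous in the Toll10b library. Of 471231 windows of 200 bp, 125846 (26.7%) were depleted in Toll10b and 84976 (18.0%) in muscle, where depleted means that the upper end of the Poisson interval of the count lay below 0.5 times the count of the flanks. The windows depleted in both numbered 67962, and 22693.5 would be shared by independent sets of these sizes. How much of this overlap is sequence to which reads cannot be assigned was not measured. At the windows depleted in Toll10b, nucleosome-sized fragments stood at 10.8% of the flanks in Toll10b and at 28.4% in muscle, and short fragments at 32.0% and 66.5%. At the windows depleted in muscle, nucleosome-sized fragments stood at 12.2% in muscle and 13.9% in Toll10b, and short fragments at 45.8% and 30.8%.

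Counting error limited which single windows could be told apart. Of the windows depleted in Toll10b, 3002 had a muscle count whose interval lay above 0.75 times its flanks, and 1128 of the windows depleted in muscle were covered in this way in Toll10b. This rule could be met at the level of the flanks by 11581 (9.20%) of the windows depleted in Toll10b and 22551 (26.5%) of those depleted in muscle, because the other windows had too few predicted fragments. By the count alone, without its interval, 9841 (7.82%) and 2854 (3.36%) reached 0.75 times the flanks in the other library. Short fragments at the windows that met the rule stood at 63.7% of the flanks in Toll10b and 166% in muscle where Toll10b was depleted, and at 127% and 42.0% where muscle was depleted. Examples chosen after their values had been seen were 2R 4125601 to 4125800, with 1 fragment in Toll10b where the flanks predicted 88.8, and 77 in muscle where they predicted 53.4, and 2R 8336401 to 8336600, with 1 of 61 in Toll10b and 43 of 35.8 in muscle. In the other direction, 2L 21594201 to 21594400 had 106 fragments in Toll10b where 77.2 were predicted, and 1 of 57 in muscle, and 3L 22165201 to 22165400 had 65 of 56.8 and 1 of 35.8.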

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

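The alternatives for the bins, the chromosome ratios and the depleted windows, and those for spacing by detrended left ends or other treatment of high-count bins, were chosen after the data had been seen; the other spacing alternatives were planned. No paired analysis was possible because each group has 1 library. The planned promoter, gene list, promoter element and promoter profile alternatives were not run, since no dm3 annotation was used, and 1 spacing alternative gave no value for Toll10b. Alternatives were run for the bin counts, the chromosome 4 and heterochromatin ratios, the depleted windows and the repeat length, and none of these reversed under them; the other results had none. By length class, the heterochromatin ratio was below 0 in the shortest class alone (-0.31). Chromosome 4 was higher in muscle throughout, with a log2 ratio of 0.84 with 1 copy of each fragment, 0.75 for fragments within 5 bp of 150 bp, 0.65 scaled by the median arm bin, 1.17 as the median bin and 1.17 without empty and high-count bins. For the heterochromatin of chromosomes 2 and 3 these values were 0.61, 0.54, 0.40, 0.98 and 0.99. Bins lower in muscle rose to 9689 when scaled by the median bin. With fragments of that length only, 1215 bins were higher and 1093 lower, of 58953 that could be tested on these fewer fragments, mainly denser bins. The count of higher bins stayed within 1.5 times under 7 of 8 alternatives, and that of lower bins under 6 of 8. A bound of 0.33 gave 82206 depleted windows in Toll10b and 46285 in muscle, fewer by construction; the other 5 settings kept each count within 1.5 times, and Toll10b had more in all. The repeat length was 183 to 185.6 bp in Toll10b under 5 alternatives and 174 to 180.1 bp in muscle under 6. The 174 bp came from left ends of all fragments, and the cause was not tested. The setting without removal of the trend gave a value in muscle alone, 179.7 bp. Fragment number limits single bins: 85% of simulated 2-fold changes on 2L were called.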

Other observations

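Apart from those of coding sequence and of bin density range, the tests below were chosen only after the results had been seen. Fragment starts on the major arms kept a 3 bp rhythm: distances that are multiples of 3 were in excess by 1.25% (1.24% to 1.27%) in Toll10b and 0.66% (0.65% to 0.67%) in muscle, with 95% intervals from the number of pairs, which are not independent. Multiples of 4, 5 and 7 showed 0.05% or less in either direction on the arms. A candidate explanation is the codon structure of coding sequence, which gives the nuclease a periodic base preference. It predicts a weaker rhythm in gene-poor heterochromatin, and there the excess was 0.14% (0.01% to 0.28%) in Toll10b and 0.03% (-0.04% to 0.10%) in muscle, at most 0.113 times that of the arms. Chromosome 4 lay between, with an excess of 0.49% (0.21% to 0.78%) in Toll10b and 0.32% (0.17% to 0.46%) in muscle. These smaller sequences are noisier than the intervals show. In Toll10b the multiples of 5 gave -0.19% in the heterochromatin and -0.35% on chromosome 4, so neither of its 3 bp values there is firm. In muscle they gave -0.03% in the heterochromatin and -0.17% on chromosome 4, so its chromosome 4 value is also less firm than its interval. Positions of exons were not analysed here, so this remains a hypothesis.

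A single bin held an unusual class of short fragments, found after its values were seen. In 3RHet 561001 to 562000, 88.5% of 15896 Toll10b fragments and 90.3% of 7797 muscle fragments were below 100 bp, against 5.35% and 19.3% on the rest of 3RHet. The most common length there was 49 bp in Toll10b and 53 bp in muscle. The bin held 49.4% of the Toll10b fragments of 40 to 79 bp in the heterochromatin of chromosomes 2 and 3. In that length class the heterochromatin had a log2 ratio of -0.31 with the bin and 0.58 (0.55 to 0.60) without it.

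Chromosome 4 and the heterochromatic sequences were relatively higher in muscle. Fragment length is argued against as the whole cause, since the chromosome 4 ratio was 0.75 among fragments within 5 bp of 150 bp and lay between 0.46, in the longest class, and 0.86, in the shortest, over all length classes, and so are a few high-count bins, since its median bin lay 1.00 above the median arm bin. A shift that is uniform along each arm is argued against by the proximal 1 Mb of 4 of the 5 arms, whose median bin lay more than 0.3 above the rest. Those bins were not matched on density, and against arm bins of like density the proximal median excess was 0.28. An effect of bin density would pass this test too, so it cannot show that the difference is regional. The narrower density range of the muscle library could account for part. Matched to arm bins of like density, chromosome 4 lay 0.50 higher, just under the bound of 0.5 set beforehand for excluding it. The heterochromatin of chromosomes 2 and 3 lay 0.39 higher by the same matching, so that this explanation stays open. Base composition was not analysed, and the extent of digestion and copy number were not measured. How reads with several matches were placed is not given in the sources used here. Stage, tissue, genotype and cell sorting also differ together between the libraries. An accessibility or occupancy change in heterochromatin may be present but cannot be separated from any of these.

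The empty bins cannot be put down to depth: 101 arm bins were empty in 1 library, where Poisson counting from the other library gives 5.01e-18 for Toll10b and 3.72e-22 for muscle. Repeated sequence stays open: 60.4% of them had 0.5 to 2 times the median count of the arms in the library that covered them, but reads of a repeat placed at 1 of several sites would give such counts too, and how they were placed is not given in the sources used here. A candidate explanation is DNA that differs between the fly stocks, such as deletions or insertions against the reference; the absence of Toll10b coverage from 3L 32806 and 2R 21139699 out to the tips would go with shortened chromosome ends in that stock. No DNA control of either stock was analysed here, so this was not tested. Unlike handling of reads with several matches in the 2 files stays open too.

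Depleted windows were more numerous in Toll10b, and the number of nucleosome-sized fragments is argued against as the cause: after thinning to equal numbers the ratio of Toll10b over muscle was 1.41. A difference in digestion or in sequence preference of the nuclease could contribute, and neither was tested. How the mixture of cell states in whole embryos bears on the number was not tested either.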
